A study of Homo sapiens with 9 samples.

How the data were processed

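Total RNA from 9 human cell cultures was measured on Illumina BeadChip arrays, on which each probe is carried by many beads and read as 1 mean brightness. The arrays fall into 3 groups by the labels: mesenchymal stromal cells (MSCs) from lung (n = 4), lung fibroblasts (n = 3) and MSCs from cord blood (n = 2). The labels call the samples of a group biological replicates and name no donors, so p-values measure the spread between these samples.

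The deposited table holds, per the file headers, an average signal for each probe and array, which is a linear intensity with no background subtracted and no scaling between arrays. It also holds the number of beads and a detection p-value for each probe and array, both deposited by the authors. Signals ranged from 29.8 to 35119.8, and each rested on 4 to 82 beads. GenomeStudio is named in the submitters' processing notes. Its version, the genome build and the annotation are not given in the sources used here. A second deposited table holds the authors' processed intensity values of the same arrays. Each of its columns equalled the unscaled signal times 1 factor per array, between 0.788 and 1.20, which brought every array to a mean of 408.88. These values are therefore linear and not centred, and they have no direction of their own. Their medians were 62.3, 61.7, 61.1 and 66.6 for lung MSC 1 to 4, 61.7, 61.8 and 59.3 for lung fibroblast 1 to 3, and 63.6 and 68.9 for cord blood MSC 1 and 2.

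Signals were background corrected, quantile normalised and log2 transformed with neqc of limma 3.58.1 in R 4.3.3. The table used here holds no control probes, so neqc inferred their distribution from the detection p-values, which moved in steps of 1 in 664. The offset was 16. Of 24526 probes, 21834 carried 1 gene symbol in the platform annotation used here and 2692 were left unnamed. XIST and Y-linked genes (67 probes) were left out. A probe was tested when its detection p-value was under 0.05 on at least 2 arrays, which left 14540 probes, 13225 of them named, for 10992 genes. Arrays detected between 12472 and 14047 probes (50.9% to 57.3%). The number of arrays limits the precision.

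Each probe was fitted with limma (lmFit, contrasts.fit and eBayes) over all 9 arrays with a mean for each group, so the 3 groups share 1 estimate of the spread (6 residual and 2.72 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe passed at an adjusted p under 0.05. "Rose" and "fell" are used only of probes past this threshold. Differences are on the log2 scale with the standard error (SE) of the fit. Where a gene had several probes, the one with the highest mean over the 9 arrays stands for it. Disagreeing probes are mentioned for the largest changes, the HOX genes and the list the study itself had singled out. A probe not detected on any array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean of normalised log2 values and the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. This bound accounts for the missing detection only and leaves out the standard error.

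Lung MSC arrays lay on 3 slides that held no other group, while the fibroblast and cord blood arrays shared a slide. Comparisons with lung MSCs were therefore also fitted with the slide as a random block (duplicateCorrelation, statmod 1.5.0). No comparison with lung MSCs lies within a slide, so this block does not separate a difference between slides from one between groups. The comparison of fibroblasts with cord blood MSCs lies within 1 slide and was also fitted on those 5 arrays alone.

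Before the data were examined, 33 gene lists were fixed, covering position genes, lung mesenchyme, inflammation, matrix, growth and markers of other cell types. Each list with at least 5 measured members was tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, whose directional test asks whether the genes of a list move one way on balance and whose mixed test asks whether they change in either direction. Members past the threshold were also counted with p-values adjusted over the list alone. With the slide as a random block, the lists were tested with cameraPR, a form of camera that takes the t statistics of the fit. The HOX genes were in addition summarised as a distance between each lung MSC array and the arrays of each other group. It is the root mean square difference over the genes, averaged over the arrays of that group. The difference between the distances to cord blood MSCs and to fibroblasts was set against all splits of the 5 other arrays and against 10000 random gene lists matched on mean level.

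The genes named in the text follow a rule fixed at the same time. For each comparison it takes the 8 largest increases and 8 largest decreases among probes that passed, with groups that do not overlap and detection on every array of the brighter group. It adds every HOX gene that passed, every gene of the list the study itself had singled out, and up to 4 members with the smallest adjusted p from each other list described. From the last part only members with an adjusted p under 0.1 are named, a limit chosen after the values were seen, and other names chosen after the values of a comparison were seen are marked there.

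The scripts were tested on simulated data: 5 simulations for each comparison on the 14540 probes, 200 of them changed. For lung MSCs against cord blood MSCs, 62.4% of 2-fold, 93.4% of 4-fold and 98.5% of 16-fold changes were recovered, and 4.06% of the calls were false. For lung MSCs against fibroblasts, the shares were 72.8%, 95.2% and 99.4%, with 5.16% false. For fibroblasts against cord blood MSCs, they were 49%, 90.4% and 98.5%, with 3.89% false. A changed list was found in 5 of 5 simulations of each comparison, and no other list was called. The simulated probes varied independently of each other, with the same spread in every group and no difference between slides. These results therefore do not show how the list test behaves when the genes of a list vary together.

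The alternatives tried were other background corrections, median scaling in place of quantiles, the authors' scaled values, no filter or a stricter filter on dim probes, the slide as a random block, the replicate number as a block, only the compared groups in the fit, array weights, a trended and robust prior, a minimum of 2-fold, an estimated correlation for the lists, other HOX distance measures, and each array left out in turn.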

Results

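Gene expression was measured in 4 cultures of lung MSCs, 3 of lung fibroblasts and 2 of cord blood MSCs. MSCs are plastic-adherent cells that can form bone, fat and cartilage cells in culture. The study grew its lung MSCs from tracheal aspirates and asked whether they come from the lung. Lung fibroblasts stand here as a resident mesenchymal cell of the organ and cord blood MSCs as an MSC from elsewhere. Mean raw signals of the arrays lay between 341.79 and 519.05, with 12472 to 14047 probes detected.

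The first principal component of all tested probes held 41.1% of the variance and parted cord blood MSCs from both lung groups, and the second held 16.8%. Lung MSC arrays correlated with each other array of their group at a mean of 0.955 to 0.966 with the fibroblast arrays at 0.955, 0.960, 0.955 and 0.971 and with the cord blood arrays at 0.919, 0.920, 0.948 and 0.930 for lung MSC 1 to 4. Lung MSC 4 thus correlated more with fibroblasts than with its own group (0.966), and lung MSC 1 about equally with both. The 3 fibroblast arrays correlated at means of 0.983 to 0.986. Spread within a group, as the root mean variance per probe, was 0.416 in lung MSCs, 0.262 in fibroblasts and 0.410 in cord blood MSCs on the log2 scale.

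**Figure D1:**
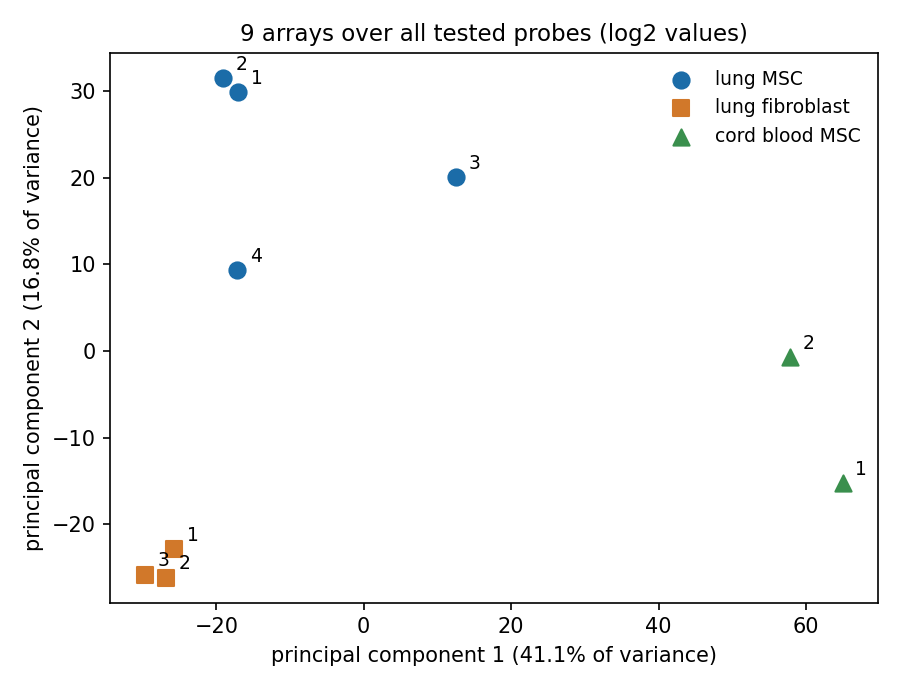
Scores of the 9 arrays on the first and second principal components of the log2 values (no unit), with the share of variance on each axis and 1 point per array coloured by group. Lung MSC 3 has a first-component score of 12.54, while the other lung MSC arrays lie between -19.06 and -17.

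Lung MSCs were compared with cord blood MSCs to ask what sets MSCs from lung apart from MSCs of another source. The transcription factors FOXF1, HOXB5 and TCF21 were far higher in the lung cells. FOXF1, a forkhead factor needed for lung and foregut mesenchyme, rose by 5.26 ± 0.38 (SE, n = 4 and 2, adjusted p = 0.00025), at least 29.8-fold. HOXB5, a position gene, rose by 6.45 ± 0.84 (adjusted p = 0.00496), at least 79.2-fold. TCF21, a factor of visceral mesenchyme, rose by 5.05 (adjusted p = 0.00391), at least 24.7-fold, with 3 probes between 3.32 and 5.05. Cord blood MSCs had far higher levels of IRX3, a homeobox factor, HAPLN1 and COL11A1.

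In all, 735 probes for 601 genes passed, 319 higher and 416 lower in lung MSCs (360 higher and 341 lower with the authors' scaled values), and 515 of them differed by at least 2-fold. The spread behind these calls also rests on the fibroblast arrays, which varied least, and 251 probes passed with only the 2 groups compared. Among the largest increases were also SPON2, a secreted matrix protein (4.95, at least 21.9-fold, adjusted p = 0.0015), LITAF (4.73 ± 0.25, adjusted p = 7.31e-05), RARRES2, the secreted chemerin (5.05, adjusted p = 0.0258), GPR37 (4.64, at least 19.1-fold, adjusted p = 0.0382) and ROR2, a receptor for WNT5A (4.52, at least 18.8-fold, adjusted p = 0.000985). RARRES2 was detected on 1 of 2 cord blood arrays. The largest decreases were in RGS4, a regulator of G-protein signalling (-5.83, adjusted p = 0.00748), SHISA2 (-5.69, adjusted p = 0.00103), ITGA10, a collagen-binding integrin chain (-5.32, adjusted p = 5.13e-05), HAPLN1, the cartilage link protein (-5.30, adjusted p = 0.00395), SORBS2 (-5.22, at least 28.3-fold lower, adjusted p = 5.13e-05), IRX3 (-5.18, adjusted p = 0.000122), MAB21L2 (-5.11, adjusted p = 0.00025) and COL11A1, a minor fibrillar collagen (-4.80, adjusted p = 0.00218). Of the 4 lung MSC arrays, 1 detected SHISA2, 1 HAPLN1, 1 COL11A1, 2 ITGA10, 2 MAB21L2 and 3 IRX3. The other MAB21L2 probe differed by -1.61.

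Position genes were read by cluster. In the HOXB cluster 4 of 8 measured genes rose, none fell and 4 did not pass, with the same 4 when adjusted over the list alone. Besides HOXB5 these were HOXB7 (4.02, at least 11.4-fold), HOXB3 (2.49, at least 3.98-fold) and HOXB4 (2.39, at least 3.94-fold). Camera placed the cluster above other genes (median 1.66, adjusted p = 0.00147), with an adjusted p of 0.254 with an estimated correlation. HOXA2, the 1 measured gene of the A cluster, rose by 2.25 (at least 3.45-fold, adjusted p = 0.0152), but did not pass without either cord blood array or with only the 2 groups compared. Of 4 HOXC and 3 HOXD genes measured, none passed. Transcription factors of limb and trunk position moved down (median -0.34, camera adjusted p = 0.00147, or adjusted p = 0.254 with an estimated correlation): 7 of 18 fell and none rose, or 8 lower and 1 higher when adjusted over the list alone. Those that fell were IRX3, IRX5 (-2.91, at least 5.62-fold lower), TBX15 (-3.01, at least 6.67-fold lower), SIX2 (-1.72, at least 2.55-fold lower) and, named after their values were seen, NKX3-2, DLX1 and TWIST1. Without either cord blood array 1 of the list fell, with 15 of the 18 still measured.

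Of 7 genes the study had singled out on these samples, 4 rose in lung MSCs over cord blood MSCs, or 5 when adjusted over the list alone. That list is not independent evidence of its direction. Beside FOXF1, the T-box factor TBX2 rose by 3.56 (adjusted p = 0.00774), the signal protein WNT5A by 2.82 (adjusted p = 0.0141) and TBX3 by 2.22 (adjusted p = 0.0258), although another TBX3 probe gave 0.21. GLI2, a hedgehog effector (1.02, adjusted p = 0.0873), and the cytokines IL6 (1.58, adjusted p = 0.246) and CXCL8 (1.92, adjusted p = 0.274) did not pass, and without cord blood MSC 1 the list had 2 that rose. Camera gave the list an adjusted p of 1.96e-06, with a median of 2.22 and an adjusted p of 0.132 with an estimated correlation. Among 17 other lung mesenchyme genes, FOXF2 (4.33, adjusted p = 0.0026) and TCF21 rose, RARB, a retinoic acid receptor, fell by 1.16 (adjusted p = 0.00667), and 14 did not pass, among them SFRP1 (4.81, at least 21.9-fold, adjusted p = 0.063). Adjusted over the list alone, 6 were higher and 1 lower. The list lay above other genes (median 1.16, adjusted p = 0.00585, or adjusted p = 0.254 with an estimated correlation). Its mean level was 6.10 in lung MSC 3, between the 5.36 and 5.43 of the cord blood arrays and the 7.11 to 7.24 of the other lung MSC arrays, and without lung MSC 3 the members that rose numbered 6. RARB did not pass without cord blood MSC 1.

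Matrix genes went both ways between lung MSCs and cord blood MSCs. Of 29 fibrillar and matrix genes, 4 rose, 5 fell and 20 did not pass, or 6 higher and 7 lower when adjusted over the list alone. The proteoglycan DCN rose by 3.92 (adjusted p = 0.00391), and so did FBLN5 (2.59, adjusted p = 0.0131) and, named after their values were seen, COL6A3 and FBLN1. COL11A1, FN1 (-2.56, adjusted p = 0.00842), POSTN (-1.70, adjusted p = 0.00786), FBN1 (-1.41, adjusted p = 0.0449) and, also named afterwards, COL5A2 fell. Without either cord blood array 1 of the list rose, and 1 fell without cord blood MSC 1, or 3 without lung MSC 4 or any 1 fibroblast array. The microfibril gene MFAP4 rose by 3.21 (adjusted p = 0.000389), whereas MFAP5 fell by 4.26 (adjusted p = 0.00697). Of 18 contractile genes, MYLK (2.81, adjusted p = 0.00163) and ACTG2 (3.81, adjusted p = 0.019) rose and 16 did not pass, while without lung MSC 2 or cord blood MSC 2 only 1 rose and without lung MSC 3 also 2 fell. Camera called neither the matrix list (adjusted p = 0.508) nor the contractile list (adjusted p = 0.62). TGF-beta target genes lay lower as a group (median -0.55, adjusted p = 0.0102, or adjusted p = 0.233 with an estimated correlation). Camera did not call them with no filter on dim probes (median -0.24, adjusted p = 0.0557). PMEPA1 (-2.06, adjusted p = 0.00218), TGFB2 (-2.75, adjusted p = 0.0356) and SMAD7 (-1.48, adjusted p = 0.0403) fell, the same count as when adjusted over the list alone, and 10 did not pass. PMEPA1 kept its call in all 9 fits that each left out an array, TGFB2 in 2 and SMAD7 in 1. The count was 1 without lung MSC 1 or 4, cord blood MSC 1 or any 1 fibroblast array, and 2 in the other such fits.

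Cell-cycle genes were shifted up in lung MSCs against cord blood MSCs (median 1.21, camera adjusted p = 1.41e-06), and the adjusted p was 0.474 with an estimated correlation. AURKA, a mitotic kinase (1.95, adjusted p = 0.0204), and TYMS, of thymidylate synthesis (1.55, adjusted p = 0.0278), rose, and 24 of 26 did not pass, although 11 were higher when adjusted over the list alone. Without either cord blood array no member passed, 1 did without fibroblast 1 or 3, and 9 did without lung MSC 4. Ribosomal protein genes had a median of 0.16 (adjusted p = 0.0486, or adjusted p = 0.493 with an estimated correlation), and none of 19 passed. With median scaling that median was -0.13.

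MSC surface markers were slightly lower in lung MSCs (median -0.36, adjusted p = 0.0332, or adjusted p = 0.254 with an estimated correlation). ENG (CD105) fell by 0.70 (adjusted p = 0.0294), 13 of 14 did not pass, and adjusted over the list alone 4 were lower and 1 higher. With an array left out, ENG passed only without lung MSC 1 or 3. The epithelial list lay lower (median -1.14, adjusted p = 0.0143, or adjusted p = 0.233 with an estimated correlation). Camera did not call it with no filter on dim probes (median -0.10, adjusted p = 0.082) or with the stricter filter (median -1.54, adjusted p = 0.0648). KRT14 fell by 1.32 (at least 1.90-fold lower, adjusted p = 0.0123), and 7 of 8 did not pass, including KRT19 (-3.81, adjusted p = 0.0523) and KRT18 (-2.34, adjusted p = 0.0914). Adjusted over the list alone, 4 were lower. No member fell without either cord blood array, where KRT14 missed the detection filter, and 2 fell without lung MSC 3 or 4. KRT14 passed in the 7 other fits that left out an array. Of the leukocyte list, CSF1R (-0.84, at least 1.41-fold lower, adjusted p = 0.00541) and CD14 (-1.04, adjusted p = 0.0306) fell and 8 of 10 did not pass, or 3 lower when adjusted over the list alone (median -0.32, adjusted p = 0.011, or adjusted p = 0.317 with an estimated correlation). The 2 became 0 without cord blood MSC 2 and 1 without lung MSC 1 or 2, fibroblast 1 or 3, or cord blood MSC 1. CSF1R was not tested without either cord blood array and passed in the 7 other fits. Of 20 leukocyte genes named on the array, 10 were detected on no array, 5 on every lung MSC array and 8 on both cord blood arrays. Camera did not call the leukocyte list with no filter on dim probes (median -0.065, adjusted p = 0.0567).

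With the slide as a random block, 471 probes passed between lung MSCs and cord blood MSCs (194 higher, 277 lower), and the calls of all 10 lists stood with cameraPR. No slide held lung MSCs and another group, however, so neither these calls nor those against fibroblasts are free of slide differences. None of the 10 calls held with an estimated correlation. Fry's directional test called 11 lists and its mixed test 21, but the 11 were not all camera's. The directional test did not call the cell-cycle or ribosomal lists (fry adjusted p = 0.131 for each). It called the adipogenic (fry adjusted p = 0.000769), mesothelial (0.0164) and fetal growth (0.00494) lists, which camera did not. Single arrays moved the count: 297 probes passed without cord blood MSC 1, 412 without cord blood MSC 2, 446 without lung MSC 2, 437 and 454 without fibroblasts 1 and 3, and 1017 without lung MSC 3. GPR37 kept its call in 1 of 9 fits that each left out an array and RARRES2 in 4 of 9, while RGS4 lost its call only without cord blood MSC 1 and TBX2 only without cord blood MSC 2. The limb and trunk list lost its call without cord blood MSC 1 (adjusted p = 0.0503) or 2 (adjusted p = 0.26), as did the leukocyte list without cord blood MSC 2 (adjusted p = 0.453) and the epithelial list without cord blood MSC 1 (adjusted p = 0.136). The limb and trunk median was 0.02 without cord blood MSC 2. The MSC surface call was lost without lung MSC 3 (adjusted p = 0.0785), lung MSC 4 (adjusted p = 0.058) or cord blood MSC 2 (adjusted p = 0.186), and the ribosomal call without any 1 array except lung MSC 1 (adjusted p of up to 0.136).

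Lung MSCs were compared with lung fibroblasts to ask how they differ from another mesenchymal cell of the lung. FOXF1, TBX2 and TBX3, which rose in both lung groups over cord blood cells, did not pass here. FOXF1 differed by -0.05 ± 0.34 (SE, n = 4 and 3, adjusted p = 0.957), TBX2 by -0.73 (adjusted p = 0.47) and TBX3 by -0.27 (adjusted p = 0.769). Higher in lung MSCs were CXCL8, the neutrophil chemokine interleukin-8 (4.75 ± 0.83, adjusted p = 0.04), and HMGCS1, an enzyme of cholesterol synthesis (3.19 ± 0.28, adjusted p = 0.00394). Lower were HOXB8 (-3.22 ± 0.30, adjusted p = 0.00406) and HOXC6 (-2.51, at least 4.80-fold lower, adjusted p = 0.0246), and TMOD1, an actin-capping protein (-3.46 ± 0.12, at least 9.05-fold lower, adjusted p = 8.46e-06).

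This comparison called 140 probes for 122 genes, 74 higher and 66 lower in lung MSCs, with 96 at least 2-fold apart. Besides HMGCS1, the sterol enzymes DHCR7 (2.50, adjusted p = 0.0253), MSMO1 (2.47, adjusted p = 0.0168), MVD (2.39, adjusted p = 0.029) and SQLE (2.22, adjusted p = 0.0117) rose, while MSMO1's probes lay between 0.37 and 2.47. None of the preset lists covered sterol synthesis, and without fibroblast 2 or 3 these 4 did not pass. FABP3, a fatty acid binding protein, rose by 3.07 (adjusted p = 0.0197), and DOCK2, a Rac activator, by 2.32 (adjusted p = 0.0037) with 1 of 3 fibroblast arrays detecting it. The largest decreases were in CPA4, a carboxypeptidase (-4.19, adjusted p = 0.0299), A2M, a protease inhibitor (-3.33, adjusted p = 0.0142), CCND2, a cyclin (-3.33, adjusted p = 0.0299), RELN (-3.31, adjusted p = 0.0388), the metalloprotease ADAMTS8 (-3.17, adjusted p = 0.0405) and SNAP25 (-2.98, adjusted p = 0.016). The other SNAP25 probe gave -0.77 and did not pass. HOXB8 was detected on 1 of 4 lung MSC arrays.

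Chemokine and cytokine genes lay higher in lung MSCs than in fibroblasts as a group (median 0.84, camera adjusted p = 0.0349, or adjusted p = 0.731 with an estimated correlation). This list does not hold CXCL8, which is in the study's own list, and none of its members rose over all probes tested. TSLP fell by 0.98 (adjusted p = 0.0168) and 17 of 18 did not pass, among them CXCL6 (5.15, adjusted p = 0.0874), CXCL1 (4.07, at least 13.9-fold, adjusted p = 0.0794) and CXCL5 (3.45, at least 8.22-fold, adjusted p = 0.0925). Adjusted over the list alone, 4 were higher and 1 lower. Without either cord blood array 3 rose, and 1 did without lung MSC 1 or 4, while TSLP did not pass without fibroblast 1 or 3. In the NF-kappa-B response list, PTGS2, the inducible cyclooxygenase, rose by 1.91 (adjusted p = 0.04997) and 13 of 14 did not pass, including NFKB1 (0.70, adjusted p = 0.081). PTGS2 kept its call in 1 of 9 fits that each left out an array. When adjusted over the list alone, 6 were higher (median 0.29, adjusted p = 0.0281, or adjusted p = 0.731 with an estimated correlation). Fibrillar and matrix genes lay higher (median 0.48, or 0.27 without lung MSC 1, adjusted p = 0.0281 over all arrays, or adjusted p = 0.731 with an estimated correlation). Of 29, POSTN rose by 1.29 (adjusted p = 0.0393), none fell, and 5 were higher when adjusted over the list alone, with COL3A1 at 0.98 (adjusted p = 0.0525) and COL5A2 at 1.04 (adjusted p = 0.0794). None rose without lung MSC 1 or 4 or any 1 fibroblast array, 2 rose without either cord blood array and 3 without lung MSC 2. Mitochondrial respiration genes had a median of -0.15 (adjusted p = 0.0431, or adjusted p = 0.731 with an estimated correlation), and none of 21 passed, nor did any when adjusted over the list alone.

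Of the 7 genes the study had singled out, CXCL8 alone rose over fibroblasts, or 3 when adjusted over the list alone. That list is not independent evidence of its direction. IL6 (2.01, adjusted p = 0.171), GLI2 (1.13, adjusted p = 0.0864) and WNT5A (0.98, adjusted p = 0.293) did not pass. Among other lists, CCN1 (1.49, adjusted p = 0.016) rose and THY1 (CD90), a surface marker of fibroblasts and MSCs (-1.52, adjusted p = 0.0117), PMEPA1 (-1.11, adjusted p = 0.041) and the cell-cycle inhibitor CDKN2A (-1.73, adjusted p = 0.0393) fell. With each of the 9 arrays left out in turn, these calls held 6 times for CCN1, 7 for THY1 and 3 for PMEPA1 and CDKN2A. None of 17 lung mesenchyme, 26 cell-cycle, 10 leukocyte or 8 epithelial genes measured passed. Adjusted over the list alone, 1 leukocyte gene was higher in lung MSCs, and no lung mesenchyme, cell-cycle or epithelial gene passed. The leukocyte median was -0.07 and the epithelial median 0.11.

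With the slide as a random block, 51 probes passed between lung MSCs and fibroblasts (25 higher, 26 lower), without CXCL8 and HOXC6, and the 4 list calls stood with cameraPR. With the authors' scaled values 221 passed, 166 higher and 55 lower, and the chemokine (adjusted p = 0.221), NF-kappa-B (adjusted p = 0.0549) and matrix (adjusted p = 0.259) calls were lost. Fewer probes passed without any 1 of the 3 fibroblast arrays (28, 19 and 18 without fibroblast 1, 2 and 3, of which 14, 4 and 4 were higher and 14, 15 and 14 lower) and without lung MSC 2 (84) or 3 (87). Over all 20 alternatives the difference of HMGCS1 lay between 3.00 and 3.43, and its call held. That of DHCR7 lay between 2.18 and 2.71, but its call held in 14 and was lost, among others, with the slide block and without any 1 fibroblast array. CXCL8 lost its call without any one array of either group, with an adjusted p of up to 0.157 and a difference between 4.37 and 5.05 over all alternatives. HOXC6 kept its call in 5 of 9 fits that each left out an array. No list passed without lung MSC 1, lung MSC 4, fibroblast 2 or fibroblast 3, the chemokine list also lost its call without lung MSC 2 (adjusted p = 0.102) or fibroblast 1 (adjusted p = 0.0518), and the respiration list without lung MSC 3 (adjusted p = 0.054). Fry's directional test called 0 lists and its mixed test 14, while 2388 probes had an unadjusted p under 0.05.

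**Figure D2:**
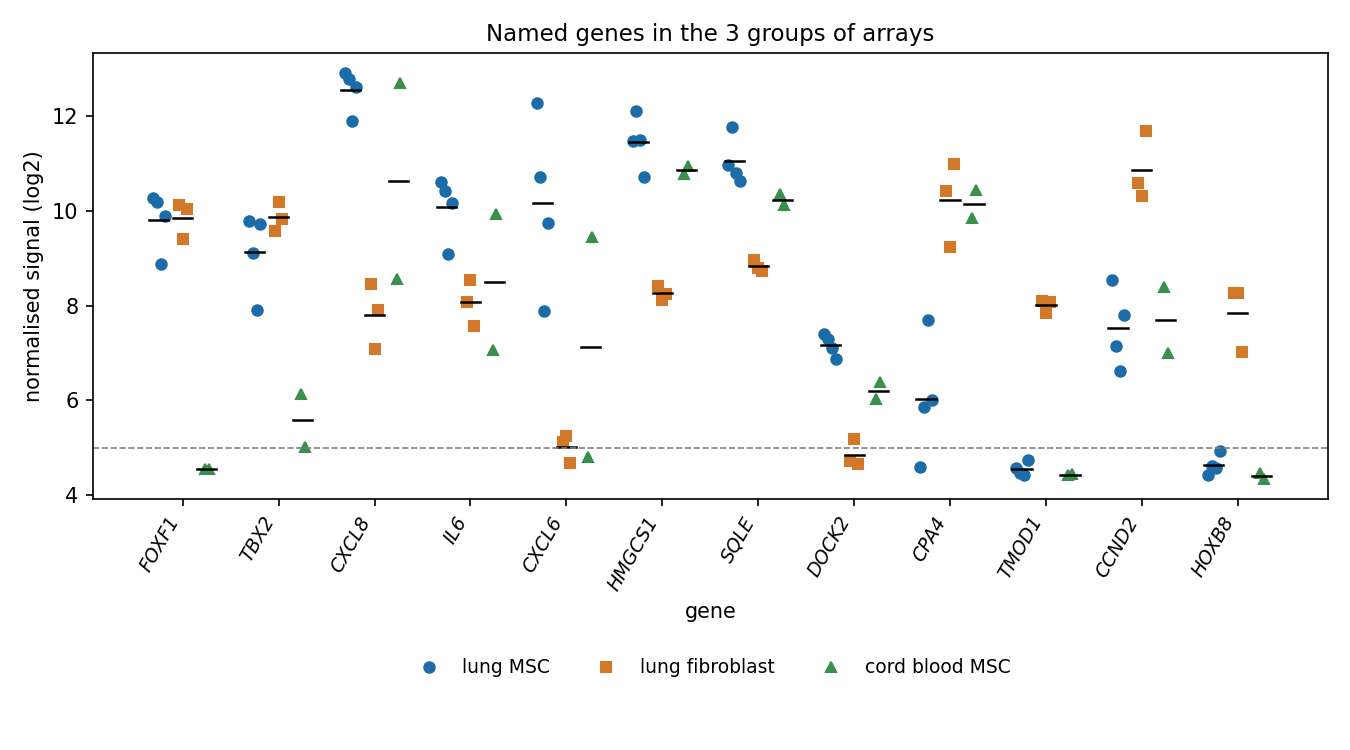
Normalised log2 signal of 12 named genes on each array, 1 point per array by group, with black bars at the group means and a dashed line at the highest, over the arrays, of the lowest signal above background. FOXF1 averaged 9.81 in lung MSCs, 9.86 in fibroblasts and 4.55 in cord blood MSCs, whereas CXCL8 averaged 12.56 in lung MSCs and 7.81 in fibroblasts.

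Lung fibroblasts were compared with cord blood MSCs, on 1 slide, as a frame for the other comparisons. In fibroblasts, FOXF1 rose by 5.32 ± 0.40 (SE, n = 3 and 2, adjusted p = 0.000316), at least 30.9-fold, HOXB5 by 7.17 ± 0.89 (adjusted p = 0.00413), at least 130-fold, and TCF21 by 5.59 (adjusted p = 0.00328), at least 35.9-fold. SFRP1, a secreted Wnt antagonist, showed the largest change, 8.37 ± 1.31 (adjusted p = 0.00895), at least 259-fold. The cord blood cells had higher IRX3 (-5.58, at least 38.2-fold lower in fibroblasts, adjusted p = 0.000113) and HAPLN1 (-5.96, at least 42.5-fold lower, adjusted p = 0.00319).

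The count was 1202 probes for 988 genes, 520 higher and 682 lower in fibroblasts (368 higher and 734 lower with the authors' scaled values), and 736 at least 2-fold apart. Further large increases were PITX1, a homeobox factor of the hindlimb (7.03, at least 110-fold, adjusted p = 0.0223), CAMK2N1 (5.32, adjusted p = 0.0101), COL15A1, a basement membrane collagen (5.11, at least 26.5-fold, adjusted p = 0.0305), and GPR37 (5.07, at least 25.9-fold, adjusted p = 0.0274). Further large decreases were RGS4 (-6.26, adjusted p = 0.00639), SHISA2 (-6.12, at least 49.2-fold lower, adjusted p = 0.000799), CRIP1 (-5.50, adjusted p = 0.000316), SORBS2 (-5.26, at least 26.5-fold lower, adjusted p = 5.59e-05), MAB21L2 (-5.15, adjusted p = 0.000316) and ITGA10 (-5.07, adjusted p = 6.62e-05). Here the other MAB21L2 probe differed by -1.64.

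Of 8 HOXB genes 5 rose in fibroblasts over cord blood MSCs, as many as when adjusted over the list alone (median 2.08, camera adjusted p = 0.000116, or adjusted p = 0.294 with an estimated correlation). Besides HOXB5 these were HOXB7 (4.64, at least 17.5-fold), HOXB8 (3.45, at least 7.69-fold), HOXB4 (2.32, at least 3.77-fold) and HOXB3 (1.83, at least 2.51-fold). HOXC6 (2.53, at least 4.54-fold) and HOXA2 (2.39, at least 3.81-fold) rose too, although neither passed without either cord blood array. From the study's own list, which is not independent evidence, TBX2 (4.29, adjusted p = 0.00452) and TBX3 (2.49, adjusted p = 0.0174) rose with FOXF1, while WNT5A (1.84, adjusted p = 0.0582), CXCL8 (-2.83, adjusted p = 0.116), IL6 (-0.43, adjusted p = 0.771) and GLI2 (-0.12, adjusted p = 0.857) did not pass. The other TBX3 probe gave 0.23 and did not pass. Adjusted over the list alone, 4 were higher and 1 lower (median 1.84, adjusted p = 0.017, or adjusted p = 0.294 with an estimated correlation). Among 17 lung mesenchyme genes TCF21, FOXF2 (4.05, adjusted p = 0.00427) and SFRP1 rose, RARB fell by 1.07 (adjusted p = 0.0101), and 7 were higher and 1 lower when adjusted over the list alone (median 0.66, adjusted p = 0.0162, or adjusted p = 0.348 with an estimated correlation). Without lung MSC 3, an array of neither group, 8 rose, and RARB did not pass without cord blood MSC 1. Of 18 limb and trunk factors, IRX3, IRX5 (-2.91, at least 5.26-fold lower), TBX15 (-2.96, at least 6.25-fold lower) and SIX2 (-1.72, at least 2.39-fold lower) fell and PITX1 rose, or 8 lower and 1 higher when adjusted over the list alone (median -0.50, adjusted p = 0.0162, or adjusted p = 0.373 with an estimated correlation). That median was -0.04 without cord blood MSC 1, -0.03 without cord blood MSC 2 and -0.003 with no filter on dim probes. Without either cord blood array 1 of the 15 still measured fell and none rose, none rose without fibroblast 1 or 3, and 2 rose without lung MSC 1.

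Of 29 fibrillar and matrix genes, 10 were lower and 5 higher in fibroblasts than in cord blood MSCs and 14 did not pass, or 14 lower and 5 higher when adjusted over the list alone. POSTN fell by 2.99 (adjusted p = 0.000799), and so did COL11A1 (-3.83, adjusted p = 0.00635) and COL5A2 (-2.29, adjusted p = 0.00336). DCN (4.54, adjusted p = 0.00261), COL15A1 and, named after their values were seen, FBLN1, FBLN5 and COL6A3 rose. Without fibroblast 1 or 3 only 6 fell and without cord blood MSC 1 only 4, and 2, 3 and 3 rose without fibroblast 1, 2 and 3, and 2 and 1 without cord blood MSC 1 and 2. Camera gave this list an adjusted p of 0.0261 (median -0.97), with an adjusted p of 0.447 with an estimated correlation. It lost its call with median scaling (adjusted p = 0.0568) and with the authors' scaled values (adjusted p = 0.128). TGF-beta targets lay lower (median -0.47, adjusted p = 0.00669, or adjusted p = 0.274 with an estimated correlation). CCN1 (-1.68, adjusted p = 0.0054), SMAD7 (-2.09, adjusted p = 0.0113), TGFB2 (-3.30, adjusted p = 0.0183) and PMEPA1 (-0.95, adjusted p = 0.0418) fell, and 6 were lower when adjusted over the list alone. Without fibroblast 1 or 3 or either cord blood array 2 fell. Cell-cycle genes lay higher (median 1.25, adjusted p = 4.35e-06, or adjusted p = 0.436 with an estimated correlation). AURKA (3.15, adjusted p = 0.00362), TYMS (1.52, adjusted p = 0.0292) and CDC20 (2.05, adjusted p = 0.0408) rose, and 10 were higher when adjusted over the list alone. Without any 1 fibroblast or cord blood array 1 rose, and 8 and 10 rose without lung MSC 4 and 2.

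Small shifts upward in fibroblasts over cord blood MSCs were called for ribosomal protein genes (median 0.19, adjusted p = 0.0162, or adjusted p = 0.387 with an estimated correlation) and respiration genes (median 0.26, adjusted p = 0.0106, or adjusted p = 0.294 with an estimated correlation), with no member past the threshold. Among epithelial markers KRT14 (-1.33, at least 1.78-fold lower, adjusted p = 0.0117), KRT18 (-2.86, adjusted p = 0.0468) and KRT7 (-2.09, at least 3.27-fold lower, adjusted p = 0.0469) fell, or 6 were lower when adjusted over the list alone (median -1.44, adjusted p = 0.0106, or adjusted p = 0.274 with an estimated correlation). None fell without cord blood MSC 1, and 1 did without lung MSC 2 or 4, cord blood MSC 2 or any 1 fibroblast array. KRT14 was not tested without either cord blood array and passed in the 7 other fits, as did CSF1R below. Among leukocyte markers CSF1R (-0.84, at least 1.32-fold lower, adjusted p = 0.00624) and CD34 (-0.84, adjusted p = 0.033) fell, or 4 were lower when adjusted over the list alone (median -0.32, adjusted p = 0.0224, or adjusted p = 0.373 with an estimated correlation). The leukocyte median was -0.10 without cord blood MSC 2, and camera did not call the list with no filter on dim probes (median -0.08, adjusted p = 0.0686). None fell without cord blood MSC 2, and 1 did without cord blood MSC 1 or any 1 fibroblast array. The interferon response list lay lower (median -1.76, adjusted p = 0.00669, or adjusted p = 0.563 with an estimated correlation), with none of 20 members past the threshold and none when adjusted over the list alone. Without cord blood MSC 1, 13 members fell, and without cord blood MSC 2 the median was 0.15.

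Within their shared slide alone, 1955 probes passed between fibroblasts and cord blood MSCs, while the limb and trunk list lost its call (adjusted p = 0.168). Over all 9 arrays, fry's directional test called 13 lists. It did not call the cell-cycle (fry adjusted p = 0.0855), matrix (0.051) or interferon (0.246) lists. It did call the adipogenic, senescence, mesothelial and fetal growth lists, which camera did not. Counts without fibroblasts 1, 2 and 3 were 426, 560 and 421, and without cord blood MSC 1 and 2 they were 463 and 534. PITX1 and COL15A1 kept their calls in 5 of 9 fits that each left out an array and GPR37 in 4 of 9. Cord blood MSC 1 decided the call of the study's own list (adjusted p = 0.205 without it), and each cord blood array decided that of the limb and trunk list (adjusted p = 0.205 and 0.606). The leukocyte call was lost without fibroblast 2 (adjusted p = 0.0549) or cord blood MSC 2 (adjusted p = 0.594).

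Both lung groups were set against the same 2 cord blood arrays, so their differences share chance values. Across 14540 probes, which are not independent replicates, the 2 sets of differences correlated at 0.824, against 0.630 in 100 simulations of unchanged groups with shared controls. Their covariance was 0.407 against 0.0539, a difference of 0.353. The simulations gave every group the same spread, whereas the spread within a group was 0.410 in cord blood MSCs and 0.262 in fibroblasts. Both simulated values may therefore be too low. Of the probes higher than in cord blood, 190 were shared between the 319 of lung MSCs and the 520 of fibroblasts, where independent lists would share 11.4. Of those lower, 286 were shared between 416 and 682, where independent lists would share 19.5. HOXB5, FOXF1, TCF21, IRX3, SORBS2 and HAPLN1 are among the genes named in both. Simulated unchanged groups, in which next to nothing can pass, shared 0 calls in 10 limma fits. Neither that count nor the overlap of independent lists, which leaves out the shared arrays, tests a shared change. The 2 cord blood arrays cannot be split further, so part of the excess may come from them.

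The HOX pattern was also read as a distance, to ask which group the lung MSCs lay nearer to. Of 39 HOX genes listed, 29 were named on the array and 16 were measured. Over these, lung MSC arrays lay at a mean root mean square distance of 1.27 from fibroblasts and 2.21 from cord blood MSCs, a difference of 0.944 ± 0.616 (SD, n = 4). Squares give large differences more weight, and HOXB5 (6.45) and HOXB7 (4.02) differed most between lung MSCs and cord blood MSCs. HOXB8, HOXC6 and HOXC8 instead stood near the cord blood level in lung MSCs. In lung MSCs their means were 4.63, 4.58 and 4.54, and in cord blood MSCs 4.40, 4.57 and 4.55. In fibroblasts they were 7.85, 7.09 and 5.965. Adjusted over the list alone, 3 of 4 HOXC genes were lower in lung MSCs than in fibroblasts. The HOX pattern was thus split. All 4 arrays lay nearer to the fibroblasts, and 3 did under 5 alternatives, where lung MSC 1 lay nearer to the cord blood MSCs. The differences were 1.19, 1.18 and 1.37 for lung MSC 2, 3 and 4 and 0.0289 for lung MSC 1, whose HOXB5 and HOXB7 levels were the lowest of the group. The value of lung MSC 1 was -0.158 with normexp and an offset of 50, -0.105 with no background correction, -0.114 with median scaling, -0.116 with the authors' scaled values and -0.114 without fibroblast 3. The real split was the most extreme of 10 (exact two-sided permutation p = 0.1, the smallest this design allows). The difference lay at percentile 97.7 of 10000 random gene lists of like level, whose median was 0.135 and 95th percentile 0.744. Random genes were drawn singly, whereas the HOXB genes varied together (estimated correlation 0.34), so this percentile may be too high. HOXB5 and HOXB7, among others, were detected on no cord blood array and passed the detection filter only through the lung groups. Without lung MSC 1 the difference was 1.25.

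**Figure D3:**
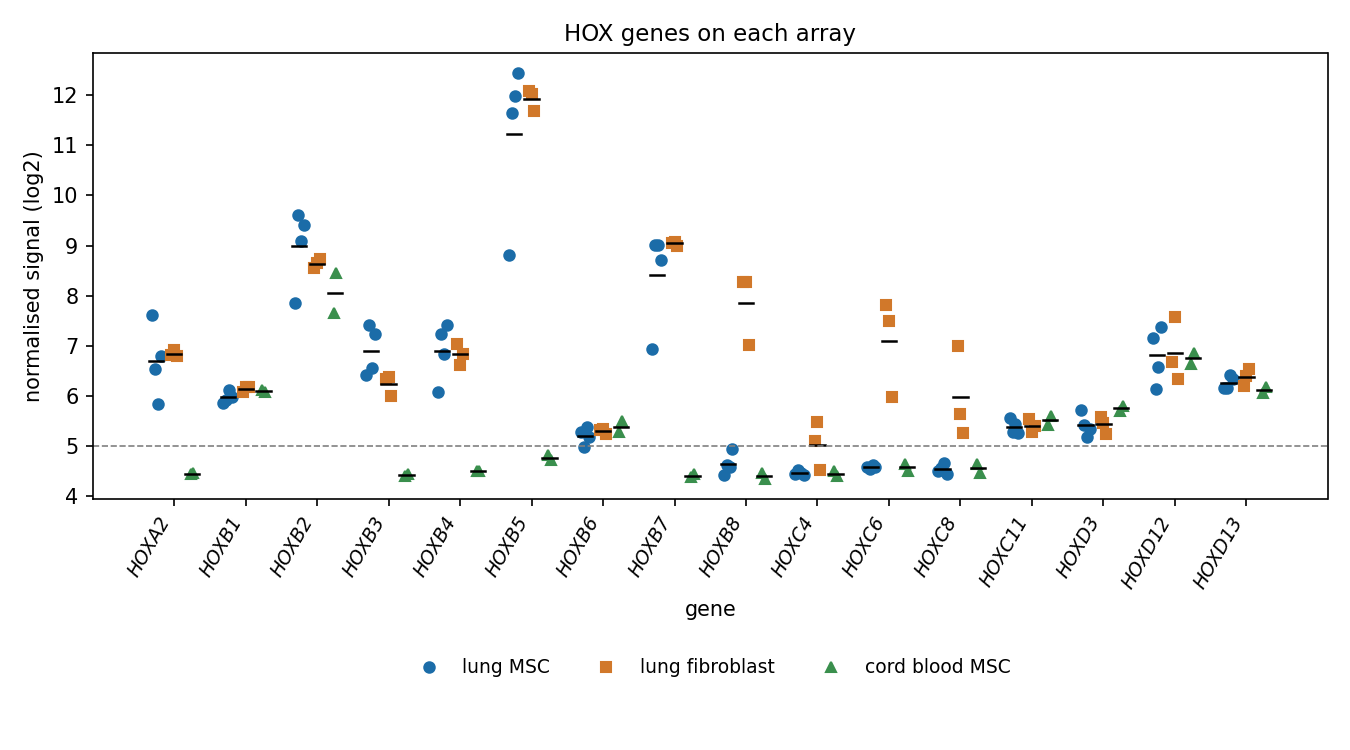
Normalised log2 signal of the HOX genes on each array, 1 point per array by group, with black bars at the group means and a dashed line at the highest, over the arrays, of the lowest signal above background. HOXB5 averaged 11.22 in lung MSCs, 11.93 in fibroblasts and 4.77 in cord blood MSCs, and HOXB8 averaged 4.63, 7.85 and 4.40.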

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

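The tests of mixed-in RNA, of a dim array and of a wrong label below were chosen only after the result was seen, and the count of splits was planned. A lung MSC array is named here when its gap to the nearest of the other 3 took up so much of the range of all 4 that it passed Dixon's critical value. Chance alone does so for about 1 in 20 groups, and 11 of 169 measures did.

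Lung MSC 3 lay between the other lung MSC arrays and the cord blood MSCs, with a first-component score of 12.54 against -19.06 to -17 and a mean of 6.10 over the lung mesenchyme list against 7.11 to 7.24. Its log2 level of the transcription factor CEBPD was 10.32 against 11.95 to 12.18, and that of IGFBP5, a binding protein of insulin-like growth factors, was 11.81 against 13.13 to 13.31. Cord blood RNA mixed into this sample would need a share of 50.6% to dim 150 lung-type probes as far as seen, yet 16 probes detected in cord blood MSCs and in no other lung MSC reached a median of 0.656% of the cord blood level (upper quartile 2.02%), which argues against it, although 5 of the 16 were detected in lung MSC 3. A dim array is argued against by its 13400 detected probes, within the 12958 to 14047 of the other lung MSC arrays. A cord blood MSC sample under this label is argued against by the same 16 probes, whose upper quartile of 2.02% is far from the full level. Yet over 267 probes that part cord blood MSCs from the other 3 lung MSC arrays, lung MSC 3 lay a median of 33.3% of the way to cord blood MSCs (quartiles 7.39% and 61.1%). It lay nearer to cord blood MSCs in 89 of these, so that measure, used next for fibroblasts, would not decide by itself. A fibroblast sample is argued against by 30 probes that part fibroblasts from those 3 arrays, over which lung MSC 3 lay a median of 14.8% of the way to fibroblasts (upper quartile 25%). What stays open, untested, is a difference between cultures or donors, a sample from outside these groups under this label, and its slide, which held no other array used here and cannot be told apart from the culture; the design gives no biological explanation, and none was tested.

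Lung MSC 1 stood apart in its HOX distance and in single genes. Its HOX distances to cord blood MSCs and to fibroblasts differed by 0.0289, against 1.18 to 1.37 for the others. HOXB7 stood at 6.94 against 8.72 to 9.01 on the log2 scale. HAPLN1 (6.96 against 4.33 to 4.46) and COL11A1 (5.38 against 4.38 to 4.46) were detected on this lung MSC array alone. XBP1, a factor of the unfolded protein response, stood at 11 against 11.37 to 11.41. SIX2 was 4.51 against 4.44, below the detection level of each of these arrays. In lung MSC 4, the tetraspanin CD151 was 13.27 against 13.19.

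For lung MSCs against fibroblasts, 1 of the 35 splits of the 7 arrays, the real one, gave as many as 140 probes, and the highest other split gave 7. A count this large is thus unlikely by chance, at the smallest share that 35 splits allow. Every other split mixes the groups, which share no slide, so a difference between slides could give the same result. For the gene lists, 10 of 35 splits gave 4 or more, with up to 9 in another split, so chance cannot be excluded.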

How the results depend on the processing

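The counts of list members with an array left out were chosen only after the data were seen, and all other alternatives here were planned. Where a count moved by over 1.5 times or a direction turned, the cause was not tested unless named. Between lung MSCs and cord blood MSCs (735 probes), 471 passed with the slide as a random block, 306 with a replicate block, 251 with only the 2 groups compared, and 297 (without cord blood MSC 1) to 1017 (without lung MSC 3) with an array left out. Between lung MSCs and fibroblasts (140 probes), 51 passed with the slide block, 51 with the replicate block, 221 with the authors' scaled values, 287 with array weights, and 18 (without fibroblast 3) to 179 (without cord blood MSC 2) with an array left out. Between fibroblasts and cord blood MSCs (1202 probes), 561 passed with the replicate block, 1955 with only the 2 groups compared, 736 at 2-fold or more, by construction, and 421 (without fibroblast 3) to 1531 (without lung MSC 1) with an array left out. All other alternatives kept these counts within 1.5 times. The called lists between lung MSCs and fibroblasts numbered 7 with median scaling, 0 with the replicate block and 0 (without lung MSC 1) to 6 (without cord blood MSC 1) with an array left out, and 6 with the authors' scaled values, none of them higher. With an estimated correlation 0 lists were called in each of the 3 comparisons, where the preset one gave 10, 4 and 12.

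The replicate numbers did not pair the samples: deviations from the group means of same-numbered lung MSC and fibroblast arrays correlated at -0.0602, -0.0576 and -0.0153, so the replicate block result stands here alone, and not every array correlated best with its own number. Averaging all probes of a HOX gene changed nothing, as each had 1 probe, and the HOX difference was 0.557 as 1 minus Pearson correlation and 0.773 to 1.25 with an array left out, while lung MSC 1 alone turned nearer to cord blood MSCs under 5 alternatives (-0.158 to -0.105). Among lists that camera called and genes followed here, directions turned for the ribosomal list between lung MSCs and cord blood MSCs with median scaling (-0.13), and for FOXF1 between lung MSCs and fibroblasts with the authors' scaled values (0.071) and with an array left out (-0.27 to 0.26). With an array left out they also turned for CXCL8 between lung MSCs and cord blood MSCs (-0.15 to 3.99) and, between fibroblasts and cord blood MSCs, for IL6 (-1.86 to 1.00), GLI2 (-0.35 to 0.12) and the interferon list (-3.78 to 0.15), and the median of the limb and trunk list between lung MSCs and cord blood MSCs turned without cord blood MSC 2 (0.023); neither FOXF1 nor these 3 genes passed in its comparison. Of the named genes that passed, 23 of 60, 4 of 24 and 30 of 79 in the 3 comparisons were tested and passed under all 20 alternatives to the fit of single genes, in that order; the 4 were HMGCS1, DOCK2, TMOD1 and HOXB8. With an array left out, a lone cord blood array is assumed to vary like the other groups. Signal over background limits the low side: a gene not detected in a group has only a bound there.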

Other observations

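All tests of the sterol and fatty acid synthesis lists in this part were chosen only after the result was seen, and the rules for reading the fatty acid list and the lung MSC slides were made stricter after their values were seen. The other lists were planned. CDKN1C, an imprinted cell-cycle inhibitor, rose over cord blood MSCs by 2.65 ± 0.26 in lung MSCs (SE, adjusted p = 0.00146, at least 5.59-fold) and by 2.63 in fibroblasts (adjusted p = 0.00166, at least 5.52-fold), and IGF2BP3, an RNA-binding protein of fetal growth, rose by 1.04 (adjusted p = 0.00974) and 1.22 (adjusted p = 0.00564). MEST, an imprinted gene, fell by 3.31 in lung MSCs (adjusted p = 0.0208). Of 12 fetal growth and imprinted genes, 2 rose and 1 fell in lung MSCs and 3 rose in fibroblasts, and camera did not call the list (adjusted p = 0.15 and 0.127). Fry's directional test called it in both (fry adjusted p = 0.00494 and 0.00395). From the senescence list, which also holds CDKN1C, IGFBP5 rose by 2.61 (adjusted p = 0.0384) and 4.15 (adjusted p = 0.00686), and IGFBP7 fell by 3.25 in lung MSCs (adjusted p = 0.0141). With each of the 9 arrays left out in turn, the calls in lung MSCs held 9 times for CDKN1C, 8 times for IGF2BP3 and IGFBP7 (not without cord blood MSC 1), 6 times for MEST and 2 times for IGFBP5.

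Of 9 pericyte and smooth muscle genes, 1 rose, 2 fell and 6 did not pass in lung MSCs over cord blood MSCs, and 1 rose, 3 fell and 5 did not pass in fibroblasts. In fibroblasts none fell without fibroblast 2 or 3 or cord blood MSC 1, 1 fell without fibroblast 1, and none rose without either cord blood array. KCNJ8, a channel of pericytes, rose in lung MSCs (1.72, adjusted p = 0.00721, at least 2.72-fold) and in fibroblasts (1.49, adjusted p = 0.0134, at least 2.32-fold), whereas RGS5 (-2.67, adjusted p = 0.0327, and -2.82, adjusted p = 0.027) and CSPG4, the NG2 proteoglycan (-1.67, adjusted p = 0.0376, and -2.03, adjusted p = 0.0187), fell in both. NES, the intermediate filament nestin, rose by 3.29 (adjusted p = 0.0108) and 3.64 (adjusted p = 0.00754), although it did not pass without cord blood MSC 1 (adjusted p = 0.0848 and 0.0504). In lung MSCs the calls held in 9 (KCNJ8), 3 (RGS5) and 4 (CSPG4) of 9 fits that each left out an array. The adipogenic factor CEBPD rose by 2.54 (adjusted p = 0.0258) in lung MSCs and by 2.54 (adjusted p = 0.0261) in fibroblasts, in 4 and 5 such fits. In fibroblasts, ALPL, the alkaline phosphatase of bone cells (3.61, adjusted p = 0.0464), and PPARG, a factor of fat cells (3.44, adjusted p = 0.0408), rose over cord blood MSCs, each in 3 such fits. Against cord blood MSCs, camera called neither the pericyte (adjusted p = 0.15 for lung MSCs and 0.119 for fibroblasts), adipogenic (0.0514 and 0.0799), osteogenic (0.928 and 0.223), chondrogenic (0.928 and 0.579), elastic fibre (0.584 and 0.976), mesothelial (0.0514 and 0.0552) and endothelial (0.728 and 0.976) lists nor the senescence (0.632 and 0.127), hypoxia (0.658 and 0.384), protease (0.928 and 0.981) and endoplasmic reticulum stress (0.872 and 0.173) lists. Of these lists, fry's directional test called the adipogenic and mesothelial lists in both lung groups and the senescence list in fibroblasts. The erythroid and neural crest lists had too few measured members to test, 2 and 4.

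The 2 cord blood MSC arrays differed in interferon response genes and in single chemokines. The mean log2 level of 20 interferon response genes was 10.26 in cord blood MSC 2 and 6.18 in cord blood MSC 1, against 6.33 to 7.94 on the other arrays. Of genes named here after their values were seen, MX1, an antiviral GTPase, stood at 13.88 and 7.88, IFIT2 at 11.86 and 7.11, CXCL8 at 12.71 and 8.56, and CCL2 at 11.52 and 5.92. With 1 array on each side there is no test.

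Enzymes of cholesterol synthesis had their lowest mean level in lung fibroblasts and their highest in lung MSCs. Of 17 measured genes of the pathway, 12 were higher in lung MSCs than in fibroblasts (median 1.85, camera p = 3.3e-22, or p = 0.0261 with an estimated correlation), and 4 were lower in fibroblasts than in cord blood MSCs (median -0.80, camera p = 1.01e-06, or p = 0.19 with an estimated correlation). Between lung MSCs and cord blood MSCs the median was 0.83 (camera p = 2.85e-06, or p = 0.207 with an estimated correlation), with 1 gene higher, or 5 without lung MSC 4 and none without fibroblast 3 or cord blood MSC 1. Mean log2 levels were 7.40 ± 0.13 in fibroblasts (SD, n = 3), 9.19 ± 0.53 in lung MSCs (n = 4) and 8.35 ± 0.08 in cord blood MSCs (n = 2). The list was drawn up after its enzymes led the comparison of lung MSCs with fibroblasts, so its p-values describe these arrays and are no independent test. The 12 fell to 2, 1 and 1 without fibroblast 1, 2 and 3, where the medians were 1.91, 1.81 and 1.83, and to 7 without lung MSC 1 or 3, and the p with an estimated correlation was 0.0533 with the authors' scaled values. The 4 fell to 1 without fibroblast 1 or 3 or either cord blood array and to 2 without fibroblast 2, and were 6 without lung MSC 2 and 7 without lung MSC 4.

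Fibroblasts and cord blood MSCs shared a slide, so by design a difference between slides is not the cause of their median of -0.803. The 2 groups were 0.762 apart there, against a largest range within a group of 0.256. Between fibroblasts and lung MSCs, which share no slide, a slide difference as the whole cause stays open. Every lung MSC array lay at least 1.06 above every fibroblast array, against ranges of 0.992 over the slides and 1.24 over the arrays of lung MSCs. Lower transcript levels of lipid synthesis as a whole stay open. Of 10 fatty acid synthesis genes, 3 were higher in lung MSCs than in fibroblasts (median 1.16, camera p = 2.51e-13, or p = 0.0181 with an estimated correlation), with 1 without fibroblast 2 or 3 and 5 without lung MSC 4. Yet 4 were also higher in lung MSCs than in cord blood MSCs (median 1.08, camera p = 4.77e-08, or p = 0.0533 with an estimated correlation), with 1 without either cord blood array, so much of that difference may be a higher level in lung MSCs. Between fibroblasts and cord blood MSCs that list had a median of -0.291, with no member past the threshold and a camera p of 0.197, which decides nothing, while the upper quartile of the sterol list there was -0.498. Culture conditions such as serum lipids, cell density or passage, and the cell type itself, remain candidate explanations that were not tested.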
